A study of Lentinus tigrinus with 27 samples.

How the data were processed

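PolyA RNA from 27 samples of Lentinus tigrinus RLP-9953-sp was made into libraries with an Illumina TruSeq RNA v2 kit, per the labels' protocols, which do not state strand. Samples were assigned to 9 groups of 3 by their titles. The labels place them on 6 sequencing flowcells. Per the submitters' processing notes, R 3.0.2, edgeR 3.4.2 and limma 3.18.13 were used. The aligner, its settings and the genome build are not given in the sources used here, beyond what the gene identifiers carry.

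The authors deposited one table per library with gene length, the count of all reads per gene, the count of uniquely mapped reads per gene and TPM, per the file headers. The deposited TPM values were recomputed from counts and lengths to within 3.5e-10, and the column of expression values equalled the total count in every row. A deposited RPKM column of these tables held no value above 0 and was not used. One further deposited table gives log2 RPKM values for 13805 genes in the 27 libraries. These are the genes with at least 5 reads in at least 7 libraries, with 0 disagreements. Within each library the deposited log2 values differed from log2 RPKM recomputed from counts by a constant between -0.271 and 0.239 (SD at most 2.2e-05 over genes with at least 50 reads). The authors therefore scaled libraries by a factor in addition to depth. The table held 0 columns of other samples.

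Of the reads of a library that were assigned to genes, between 98.543% and 99.626% mapped uniquely. In 335 genes less than 90% of the reads were unique, and such genes can share reads with near-identical copies. Reads from overlapping genes on opposite strands cannot be told apart where strand was not used. The median gene length was 1216 bases and 56.8% of lengths were multiples of 3. The reference table at hand belongs to another assembly (Lenti7_1), held 15665 genes and matched 0 of the identifiers, so no names were used. Gene lists had been planned by words in gene descriptions and could not be made.

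All tests used the total counts. Genes were filtered with edgeR's filterByExpr at a minimum count of 10, which left 13569 genes and removed 2012. Libraries were scaled by TMM, and 1 model with 9 group means was fitted to all 27 libraries with edgeR's quasi-likelihood method (edgeR 4.0.16, R 4.3.3), with 18 residual degrees of freedom. The common coefficient of biological variation was 0.343. p-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called at an adjusted p under 0.05 and a fold change of at least 2, and calls of at least 4-fold are given beside it. Standard errors of log2 fold changes were derived from the fold change and its F statistic. For the tests over 9 and over 8 groups, a 4-fold range of group means was required. Tests are two-sided. Because all groups share 1 estimate of the spread, groups with wide spread between libraries (VM, FB_cap, FB_lamellae) are tested against too small an error and the tight groups against too large an error, and fits of only the 6 libraries compared are given where they differ.

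Named genes were chosen by a rule set before the data were examined, with 2 departures. Its condition of an informative description could not be applied, and 2 genes per direction are named in place of 10. They are, per comparison, the 2 largest rises and 2 largest falls among called genes whose 3 libraries of one group all lie above the 3 of the other and whose higher group mean is at least 20 CPM. By chance 10% of genes separate in this way, and 12.9% to 52.0% did so in the 11 comparisons. CPM values are TMM-scaled.

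The functions were tested on simulated data drawn from the real means, library sizes and dispersions of 13569 genes, with 100 genes changed at each fold. For P1 against VM, 83% of 4-fold and 17% of 2-fold changes were recovered and 2 of 13369 unchanged genes were called. For FB_lamellae against FB_cap the values were 66% and 15%, with 3 unchanged genes called. The simulation gave all groups the same dispersion per gene. For the groups with wide spread (VM, FB_cap, FB_lamellae) it can therefore overstate recovery and understate false calls. For the interaction between stage 2 and the fruiting body, 37% of 4-fold and 4% of 2-fold changes were recovered. Seeded 2-fold changes lie at the fold cutoff of a call, which by itself lowers their recovery.

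No pair of libraries agreed within sampling noise, since chi-square per degree of freedom was between 43.9 and 349 within groups. The numbers of the replicates recur across groups, and whether they pair the samples was checked by the correlation of deviations from the group means over 10258 genes. Every same-number correlation exceeded 0.1 with 3 pairs only for YFB_stipe with P2_stipe (0.295 to 0.414) and YFB_cap with YFB_stipe (0.299 to 0.402). The labels do not say what a number shares. FB_stipe replicate 4 is the only library with its number and the only library on its flowcell. A replicate block or a flowcell covariate therefore leaves it out in effect.

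The alternatives set before the data were examined were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), a replicate block, flowcell as a covariate, unique reads only, the 6 libraries compared alone and leaving out each library in turn. For the RPKM rule they were a pseudocount of 1, a minimum of 1 or none, group medians and leaving out each replicate number. Added after seeing the data were a paired replicate block over P2_stipe, YFB_stipe and YFB_cap, runs without FB_cap replicate 2 and FB_lamellae replicate 1 or without the 4 libraries of 1 flowcell, 2 more interactions, and counts for every pair of groups. DESeq2 gave no adjusted p for 12 to 539 genes per result, which were left as such. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.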

Results

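Gene expression was measured across the development of Lentinus tigrinus RLP-9953-sp, a wood-decay mushroom that forms a cap on a central stipe with gills (lamellae) under the cap. The 27 polyA RNA libraries fell into 9 groups of 3. Vegetative mycelium (VM) is the growth phase before fruiting. Fruiting was started on sawdust with wheat bran, by 21 days in the dark at 30 °C followed by 25 °C with 12 h of light and 12 h of dark per day. Stage 1 primordia (P1) were white stalks of 5 to 20 mm with no cap initial. Stage 2 primordia were 15 to 25 mm tall with a brown cap initial and gave a cap (P2_cap) and a stipe sample (P2_stipe). Young fruiting bodies, 30 to 40 mm tall with a brown cap initial of up to 5 mm, gave YFB_cap and YFB_stipe. Fruiting bodies of 50 to 70 mm with a flattened cap gave FB_cap, FB_stipe and FB_lamellae. The labels describe the 3 libraries of a group as biological replicates. Those of FB_stipe carry the numbers 2, 3 and 4.

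Between 10.84 and 31.82 M reads per library were assigned to genes. The group means were lowest for FB_lamellae (13.1 ± 3.61 M reads, SD, n = 3) and highest for P2_cap (24.8 ± 9.17 M reads, SD, n = 3). Of 15581 gene models, 1337 had no read in any library and 13569 had enough reads to be tested. Gene identifiers are printed as in the files with the sign _ in place of bars. The files do not pair them with names or functions, so genes appear by identifier only, with at most 2 that were higher and 2 that were lower per comparison.

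The libraries separated first by vegetative against fruiting growth and then by tissue. The first principal component of log2(CPM + 1) held 30.8% of the variance and the second 18.6%. VM lay at one end of the first component. Along the second, P1 and all stipe libraries lay at positive values and all cap and lamellae libraries at negative values. The spread between the libraries of a group was uneven. The median SD of log2(CPM + 1) over 10258 genes was 0.20 in P2_cap and 0.22 in both YFB_cap and YFB_stipe, against 0.34 in VM, 0.40 in FB_cap and 0.40 in FB_lamellae. FB_cap replicate 2 and FB_lamellae replicate 1 lay closer to VM on the first component than the other libraries of their groups.

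**Figure D1:**
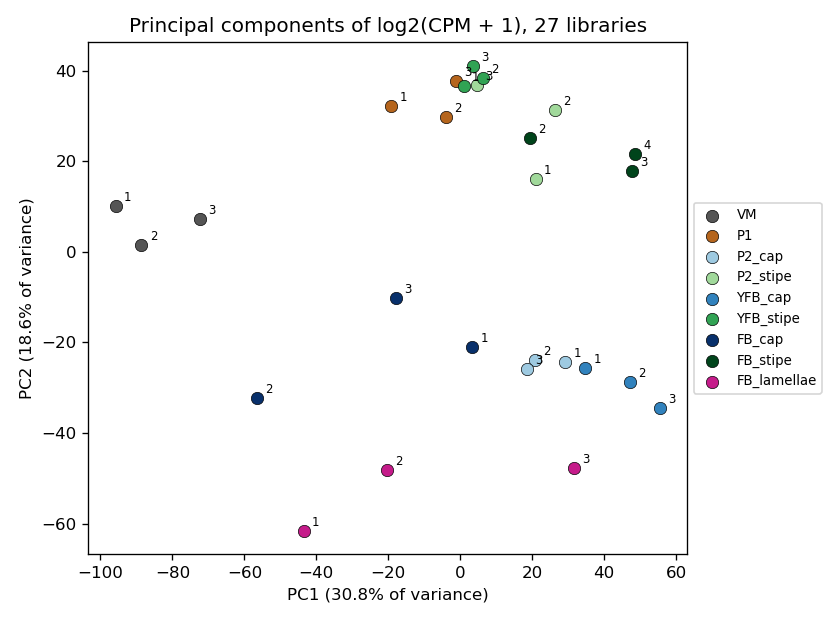
First and second principal components (unitless scores, with the percent of variance on each axis) of log2(CPM + 1) for the 27 libraries, colored by group and marked with the replicate number. P1 and the stipe libraries lie above 0 on the second component, and the cap and lamellae libraries below it.

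The step from vegetative mycelium to stage 1 primordium asks which genes respond to the onset of fruiting. In P1, 2034 of 13569 genes differed from VM by at least 2-fold at the adjusted threshold, 937 higher and 1097 lower. Large changes were mostly falls, since 525 of the 712 genes past 4-fold were lower in P1. Lenti6_1_615060 rose from 11.5 ± 10.8 CPM in VM to 951 ± 530 CPM in P1 (SD, n = 3 each), a log2 fold change of 6.37 ± 1.33 (SE, edgeR adjusted p = 0.00185). Lenti6_1_615061, of the same length (348 bases), rose from 22.5 ± 22.8 to 817 ± 693 CPM (SD, n = 3 each). Lenti6_1_580031 fell from 451 ± 469 to 1.08 ± 0.873 CPM (SD, n = 3 each), a log2 fold change of -8.81 ± 0.83 (SE, edgeR adjusted p = 5.27e-07). Lenti6_1_580637 had 3.69 ± 0.41 CPM in P1 and a wide range in VM, from 4.87 to 4483 CPM over 3 libraries.

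The labels do not say whether VM was taken from malt agar or from the fruiting medium, so medium may add to this comparison. No incubation time, temperature or light is recorded for VM here, so these may add to it as well. VM replicates 1 and 2 were sequenced on a flowcell that held no P1 library, and with flowcell as a covariate the count was 1167. The call of Lenti6_1_615061 was then lost (log2 fold change 3.81, edgeR adjusted p = 0.056), and Lenti6_1_615060 stood at 5.02. Without the 4 libraries of the flowcell of VM replicates 1 and 2, VM was left with 1 library, so no conclusion is drawn from the count. In that fit the log2 fold changes of Lenti6_1_615060 and Lenti6_1_615061 were 5.32 and 4.06. Without VM replicate 3 the balance turned to 1489 higher and 1195 lower, and without VM replicate 2 it was 579 higher and 954 lower. Without VM replicate 3 the log2 fold changes of Lenti6_1_615060, Lenti6_1_615061, Lenti6_1_580637 and Lenti6_1_580031 were 7.41, 6.35, -7.74 and -7.52. Without P1 replicate 3 that of Lenti6_1_615061 was 4.21, and without P1 replicates 1 and 2 in turn that of Lenti6_1_580031 was -9.46 and -8.20.

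The cap initial that appears in stage 2 differed strongly from the stage 1 primordium, while for the stipe beneath it edgeR called no gene. Between P2_cap and P1, 1905 genes changed, 709 higher and 1196 lower in the cap, 436 of them past 4-fold. Lenti6_1_587289 rose from 0.475 ± 0.128 CPM in P1 to 43.5 ± 18.8 CPM in P2_cap (SD, n = 3 each, log2 fold change 6.45 ± 1.41 SE, edgeR adjusted p = 0.00367). Lenti6_1_481348 rose from 0.525 ± 0.254 to 24.4 ± 9.60 CPM (SD, n = 3 each), but its call was lost without P1 replicate 1 (log2 fold change 5.18, edgeR adjusted p = 0.0579, 0.000564 to 0.0579 over the alternatives). Lenti6_1_528932 fell from 3205 ± 3660 CPM in P1 to 16.7 ± 27.5 CPM in P2_cap (SD, n = 3 each, log2 fold change -7.59 ± 1.64 SE, edgeR adjusted p = 0.00341). Lenti6_1_577109 fell from 91.5 ± 122 to 0.675 ± 0.251 CPM (SD, n = 3 each). Single libraries set the size of these falls, since without P2_cap replicate 3 the log2 fold change of Lenti6_1_528932 was -11.87, and without P1 replicate 3 those of Lenti6_1_528932 and Lenti6_1_577109 were -6.08 and -4.96. Without P2_cap replicate 1 or 3 the count was 1167 or 1255. Without P1 replicate 1 or 3, 457 or 470 genes were higher in the cap.

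Between P2_stipe and P1, edgeR called 0 genes, with 1225 of 13569 at an unadjusted p under 0.05. By chance, a share of 0.05 of the tested genes would lie there in a comparison without any change. limma-voom also called 0, and DESeq2 called 53 (14 higher and 39 lower in P2_stipe). Without P2_stipe replicate 1, 2 genes were called. In simulated counts for this comparison, 70% of seeded 4-fold changes and 20% of 2-fold changes were recovered. Small changes could therefore go unseen, both with 3 libraries per group and because a call needs an estimate of at least 2-fold.

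From stage 2 to the young fruiting body few genes were called in either tissue. In the cap, 44 genes changed between P2_cap and YFB_cap, 23 higher and 21 lower, 17 of them past 4-fold. Lenti6_1_656439 rose from 3.15 ± 0.611 to 30.2 ± 22 CPM and Lenti6_1_494052 from 8.49 ± 2.69 to 77.6 ± 54.3 CPM in YFB_cap (SD, n = 3 each), with log2 fold changes of 3.26 ± 0.63 and 3.19 ± 0.70 (SE, edgeR adjusted p = 0.0195 and 0.0463). Each of these 2 calls was lost in 6 of 14 alternatives, with the replicate block, with flowcell as a covariate and without any 1 of the P2_cap libraries or YFB_cap replicate 3 (adjusted p from 1.7e-05 to 0.228 and from 0.000229 to 0.395). Their log2 fold changes were 3.42 and 3.36 with flowcell as a covariate and 3.16 and 3.00 with the replicate block, so the folds were near those above, and 2.47 and 2.44 without YFB_cap replicate 3. Lenti6_1_246303 fell from 22.2 ± 11.4 to 3.20 ± 0.781 CPM and Lenti6_1_653596 from 121 ± 39.2 to 22.4 ± 8.35 CPM (SD, n = 3 each). Without YFB_cap replicate 3 neither was called (log2 fold changes -2.64 and -2.15, against -2.79 and -2.43), and Lenti6_1_653596 was also not called without P2_cap replicate 1 or with flowcell as a covariate (-2.17 and -2.39). The count depended on single libraries and on the fit. It was 5 without YFB_cap replicate 3, and 15, 14 and 15 without P2_cap replicates 1, 2 and 3. It was 10 with flowcell as a covariate, 68 with limma-voom, 153 with DESeq2 and 129 in a fit of these 6 libraries alone. The near balance of rises and falls also moved, to 26 and 31 without YFB_cap replicate 1 and 19 and 11 without YFB_cap replicate 2.

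In the stipe, edgeR called 0 genes between P2_stipe and YFB_stipe, with 844 at an unadjusted p under 0.05. limma-voom and DESeq2 each called 0 as well. The paired fit, with the replicate number as a block, also called 0. In simulated counts for this comparison, 75% of 4-fold and 14% of 2-fold changes were recovered.

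Maturation from young to full fruiting body changed many genes in both tissues. In the cap, 2205 genes differed between FB_cap and YFB_cap, 1432 higher and 773 lower in FB_cap, and 562 of the 651 past 4-fold were higher. Lenti6_1_584306 rose from 2.35 ± 0.982 to 446 ± 621 CPM (SD, n = 3 each, log2 fold change 7.57 ± 1.24 SE, edgeR adjusted p = 0.000802), with FB_cap libraries between 47.7 and 1161 CPM. Lenti6_1_491550 lay between 4.70 and 1319 CPM in FB_cap against 1.13 to 2.77 CPM in YFB_cap, and its call was lost without FB_cap replicate 3 (log2 fold change 2.23, edgeR adjusted p = 0.0599, 0.000718 to 0.0778 over the alternatives). Lenti6_1_615061 fell from 568 ± 192 to 14.4 ± 17.2 CPM and Lenti6_1_566055 from 635 ± 265 to 21.6 ± 31.4 CPM (SD, n = 3 each). The call of Lenti6_1_566055 was lost without FB_cap replicate 2 (log2 fold change -4.34, edgeR adjusted p = 0.0739, 0.00072 to 0.0739 over the alternatives), and that of Lenti6_1_615061 with flowcell as a covariate (log2 fold change -3.94, adjusted p = 0.0718, 1.8e-05 to 0.0718).

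No flowcell held both FB_cap and YFB_cap libraries, so no value within a flowcell can be given. With flowcell as a covariate, which compares them through the other groups, 347 genes were called. A fit of the 6 libraries alone called 552, without Lenti6_1_491550, Lenti6_1_615061 and Lenti6_1_566055, whose log2 fold changes were near those of all 27 libraries (7.86, -5.28 and -4.86) at wider errors. Without FB_cap replicate 3 the log2 fold changes of Lenti6_1_584306, Lenti6_1_615061 and Lenti6_1_566055 were 5.23, -6.91 and -7.51. The count was 1138 without FB_cap replicate 2, 1198 and 1160 without YFB_cap replicates 2 and 3, and 1272 without FB_cap replicate 2 and FB_lamellae replicate 1.

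In the stipe, 1212 genes differed between FB_stipe and YFB_stipe, 412 higher and 800 lower in FB_stipe, 218 of them past 4-fold. Lenti6_1_528874 fell from 335 ± 79.8 to 9.95 ± 2.84 CPM (SD, n = 3 each, log2 fold change -5.07 ± 0.79 SE, edgeR adjusted p = 0.00079). Lenti6_1_528932 fell from 917 ± 765 to 7.34 ± 8.57 CPM (SD, n = 3 each). Lenti6_1_580141 rose from 2.55 ± 1.54 to 39.5 ± 18 CPM, and Lenti6_1_573787 from 57.8 ± 18.8 to 880 ± 1087 CPM (SD, n = 3 each). The rise of Lenti6_1_573787 was not called without FB_stipe replicate 2 (log2 fold change 2.14, edgeR adjusted p = 0.0986, 7.28e-05 to 0.0986 over the alternatives), nor that of Lenti6_1_580141 without YFB_stipe replicate 2 (log2 fold change 3.55, edgeR adjusted p = 0.0584, 0.000291 to 0.0735 over the alternatives). The count was 505 without YFB_stipe replicate 1, 558 without FB_stipe replicate 3 and 707 with flowcell as a covariate. FB_stipe replicate 4, alone on its flowcell, in effect drops out of the covariate fit. Without YFB_stipe replicate 2, 266 genes were higher in FB_stipe. The call of Lenti6_1_580141 was also lost with flowcell as a covariate (log2 fold change 3.36). Without FB_stipe replicate 4 and YFB_stipe replicate 3 in turn, the log2 fold change of Lenti6_1_528932 was -8.57 and -6.02.

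Cap and stipe differed at every stage at which they were sampled. At stage 2, 1056 genes differed, 453 higher and 603 lower in the cap, 316 of them past 4-fold. Lenti6_1_616994 stood at 220 ± 171 CPM in P2_cap and 2.76 ± 1.23 CPM in P2_stipe (SD, n = 3 each, log2 fold change 6.31 ± 0.86 SE, edgeR adjusted p = 8.14e-05). Lenti6_1_481348, which rose in P2_cap over P1, was also higher in P2_cap than in P2_stipe (24.4 ± 9.60 against 0.234 ± 0.121 CPM, SD, n = 3 each). Its call was lost without P2_stipe replicate 2 or 3 (log2 fold changes 6.62 and 6.39, against 6.69, edgeR adjusted p = 0.0618 and 0.072, from 8.4e-05 over the alternatives). Higher in the stipe were Lenti6_1_575656, with 917 ± 583 against 21.1 ± 7.82 CPM, and Lenti6_1_601078, with 292 ± 245 against 2.88 ± 0.258 CPM (SD, n = 3 each). The count was 664 and 630 without P2_cap replicates 1 and 3, and 650 and 593 without P2_stipe replicates 2 and 3. The log2 fold change of Lenti6_1_616994 was 5.49 without P2_cap replicate 3, and that of Lenti6_1_601078 -6.06 without P2_stipe replicate 2.

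The young fruiting body had the highest count among the 11 comparisons, with 2499 genes, 930 higher and 1569 lower in YFB_cap than in YFB_stipe, 490 of them past 4-fold. Lenti6_1_575656 was again higher in the stipe, with 1926 ± 257 against 18.2 ± 6.74 CPM in the cap (SD, n = 3 each, log2 fold change -6.73 ± 0.77 SE, edgeR adjusted p = 1.44e-05). Lenti6_1_528932 reached 917 ± 765 CPM in the stipe and 0.769 ± 0.087 CPM in the cap (SD, n = 3 each). Lenti6_1_654528 was higher in the cap, with 734 ± 404 against 7.85 ± 3.81 CPM (SD, n = 3 each, log2 fold change 6.54 ± 1.41 SE, edgeR adjusted p = 0.00255), as was Lenti6_1_652575, with 59.4 ± 14.6 against 1.43 ± 0.101 CPM. The count was 1548 without YFB_cap replicate 3. The log2 fold change of Lenti6_1_528932 was -10.21, and -9.26 without YFB_stipe replicate 3.

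In the fruiting body, 1697 genes differed, and the balance was turned, with 1205 higher and 492 lower in FB_cap than in FB_stipe, 662 of them past 4-fold. Lenti6_1_580271 stood at 3952 ± 4247 CPM in FB_cap and 9.05 ± 0.948 CPM in FB_stipe (SD, n = 3 each, log2 fold change 8.77 ± 1.65 SE, edgeR adjusted p = 0.00151). Lenti6_1_577147 ranged from 18.7 to 1092 CPM in FB_cap against 0.891 ± 0.391 CPM in FB_stipe (SD, n = 3). Lenti6_1_615060 and Lenti6_1_615061, which rose from VM to P1, stood at 4760 ± 4362 and 3026 ± 2116 CPM in FB_stipe (SD, n = 3 each). In FB_cap they stood at 31.5 ± 31.8 and 14.4 ± 17.2 CPM (SD, n = 3 each). No flowcell held both tissues. FB_stipe replicate 4 was alone on its flowcell, so the covariate fit rests on FB_stipe replicates 2 and 3. With flowcell as a covariate 134 genes were called, and the calls of Lenti6_1_580271 (edgeR adjusted p = 0.183, 1.47e-11 to 0.183 over the alternatives), Lenti6_1_577147 (0.248, 1.54e-10 to 0.248) and Lenti6_1_615060 (0.087, 6.49e-11 to 0.087) were lost at log2 fold changes of 6.34, 6.51 and -4.93. Without FB_cap replicate 2 those of Lenti6_1_580271 and Lenti6_1_577147 were 7.39 and 5.31. Those of Lenti6_1_615060 and Lenti6_1_615061 were -8.30 and -9.32 without FB_cap replicate 3, and -6.20 and -7.00 without FB_stipe replicate 4. The call of Lenti6_1_577147 was also lost with limma-voom (6.87), and that of Lenti6_1_615060 in the 6 libraries alone (-7.23). The count was 415 in the 6 libraries alone, 814 without FB_cap replicate 2, 1023 and 990 without FB_stipe replicates 4 and 3, and 919 without FB_cap replicate 2 and FB_lamellae replicate 1.

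The spore-bearing lamellae were compared with the cap of the same stage. Of 327 called genes, 253 were lower and 74 higher in FB_lamellae than in FB_cap, and 119 were past 4-fold. Lenti6_1_497378 rose from 52.6 ± 34.9 CPM in FB_cap to 293 ± 218 CPM in FB_lamellae (SD, n = 3 each, log2 fold change 2.47 ± 0.48 SE, edgeR adjusted p = 0.0117), and Lenti6_1_538975 from 6.84 ± 3.39 to 38.3 ± 30.8 CPM. Lenti6_1_491550 and Lenti6_1_542513 had 1.65 ± 0.585 and 2.72 ± 0.935 CPM in FB_lamellae (SD, n = 3 each) and up to 1319 and 1738 CPM in FB_cap, but both calls were lost without FB_cap replicate 3 (log2 fold changes -2.46 and -0.77, edgeR adjusted p = 0.126 and 0.548, with 0.00136 to 0.652 and 0.00188 to 0.652 over the alternatives). Lenti6_1_491550 and Lenti6_1_542513 were also not called with flowcell as a covariate (-5.67 and -6.24), with limma-voom (-4.89 and -3.84) or without FB_lamellae replicate 3. The count of called genes moved with single libraries and with the tool. It was 38 without FB_lamellae replicate 3, 703 without FB_lamellae replicate 2, 596 without FB_cap replicate 2, 194 with flowcell as a covariate and 657 with DESeq2. In a fit of the 6 libraries alone, which uses the spread of these groups only, edgeR called 0 genes, with 1028 at an unadjusted p under 0.05. None of the 4 named genes was called in that fit, at log2 fold changes of 2.51, 2.50, -8.06 and -7.73 in the order above. Lenti6_1_538975 was also not called without FB_cap replicate 1 (2.19) or FB_lamellae replicate 3 (1.58), and Lenti6_1_497378 stood at 1.67 without FB_lamellae replicate 1. The genes higher in the lamellae numbered 15 without FB_cap replicate 1, and 147 and 167 were lower without FB_cap replicate 3 and FB_lamellae replicate 1. Without FB_cap replicate 2 and FB_lamellae replicate 1 together, 200 were higher and 238 lower.

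**Figure D2:**
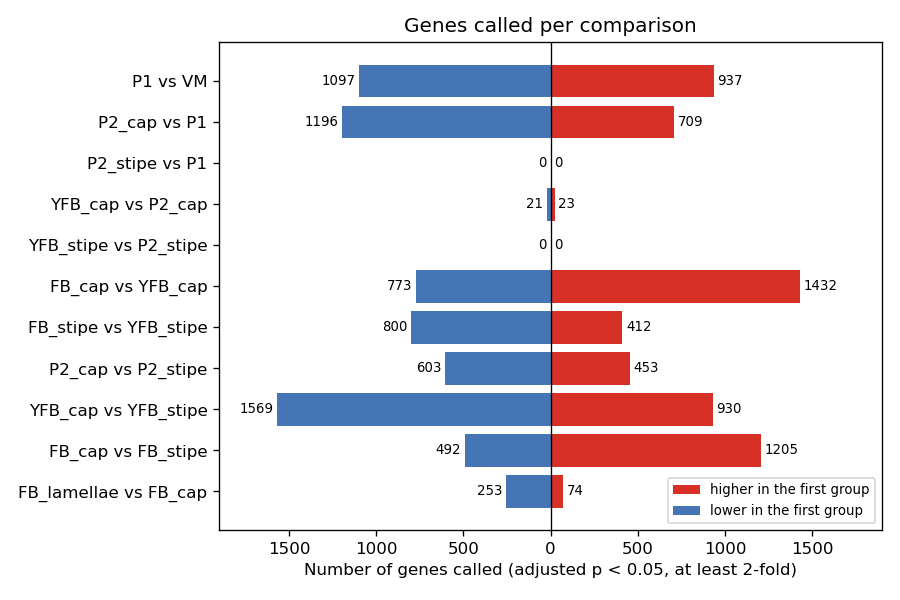
Number of genes called in each of the 11 comparisons (horizontal axis, adjusted p under 0.05 and at least 2-fold), with genes higher in the group named first to the right of 0 and genes lower to the left. The bars reach 1432 genes higher in FB_cap than YFB_cap and 1569 lower in YFB_cap than YFB_stipe, and are empty for P2_stipe against P1 and YFB_stipe against P2_stipe.

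The cap-to-stipe differences of stage 2 recurred in part in the young fruiting body, in libraries that the 2 comparisons do not share. Of 453 genes higher in P2_cap than P2_stipe and 930 higher in YFB_cap than YFB_stipe, 196 were in both lists, against 31 for independent lists. Of the genes lower in the cap, 370 were shared, against 69.7. In opposite directions at these stages, 2 and 1 genes were called, against 52.4 and 41.3. The lists of the young and the full fruiting body shared 111 genes higher in the cap against 82.6 for independent lists and 96 lower against 56.9, while 49 against 33.7 and 145 against 139.3 were called in opposite directions. Between stage 2 and the full fruiting body, 159 genes higher in the cap were shared against 40.2 for independent lists and 108 lower against 21.9, while 11 against 16.4 and 29 against 53.5 were called in opposite directions. Over the 3 stages, 67 genes were higher and 65 lower in the cap each time. Lenti6_1_575656 was among those lower in the cap, with 66.1 ± 49.3 CPM in FB_cap and 2160 ± 739 CPM in FB_stipe (SD, n = 3 each).

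Whether the cap-to-stipe difference itself changed was tested as an interaction. Between stage 2 and the fruiting body it changed for 1215 genes, 734 toward the cap and 481 toward the stipe. The count was 126 with flowcell as a covariate, where FB_stipe replicate 4 in effect drops out. It was 581 and 670 without P2_cap replicates 1 and 3, 661 without P2_stipe replicate 3, 727 without FB_cap replicate 2, and 620 and 606 without FB_stipe replicates 4 and 3. Without P2_stipe replicate 2, 303 genes moved toward the stipe.

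Across all groups, 3529 genes varied with at least a 4-fold range of group means at the adjusted threshold, and 2374 did so among the 8 fruiting groups. VM held the highest mean for 1205 of the 3529 genes (34.1%) and FB_lamellae for 518 (14.7%). P2_stipe held it for 58 (1.6%). Among the 8 fruiting groups, FB_lamellae was highest for 597 of 2374 genes (25.1%) and FB_cap for 445 (18.7%), the groups with the widest spread between libraries. FB_stipe had the lowest mean for 622 (26.2%). Leaving out any 1 library gave 3355 to 3984 genes over the 9 groups and 2235 to 2503 over the fruiting groups.

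A rule of level and fold on the deposited RPKM values, with no test, gave 2412 developmentally regulated genes (17.5% of the genes with such values). Of these, 2360 had a highest group mean of at least 4 RPKM and a range of at least 4-fold over the fruiting groups, 188 rose at least 4-fold from VM to P1, and 136 met both conditions. The 188 moved to 405 without all libraries of replicate 3 and to 308 with group medians. Of the 2360, 2109 also passed the test over the 8 fruiting groups and 251 did not.

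**Figure D3:**
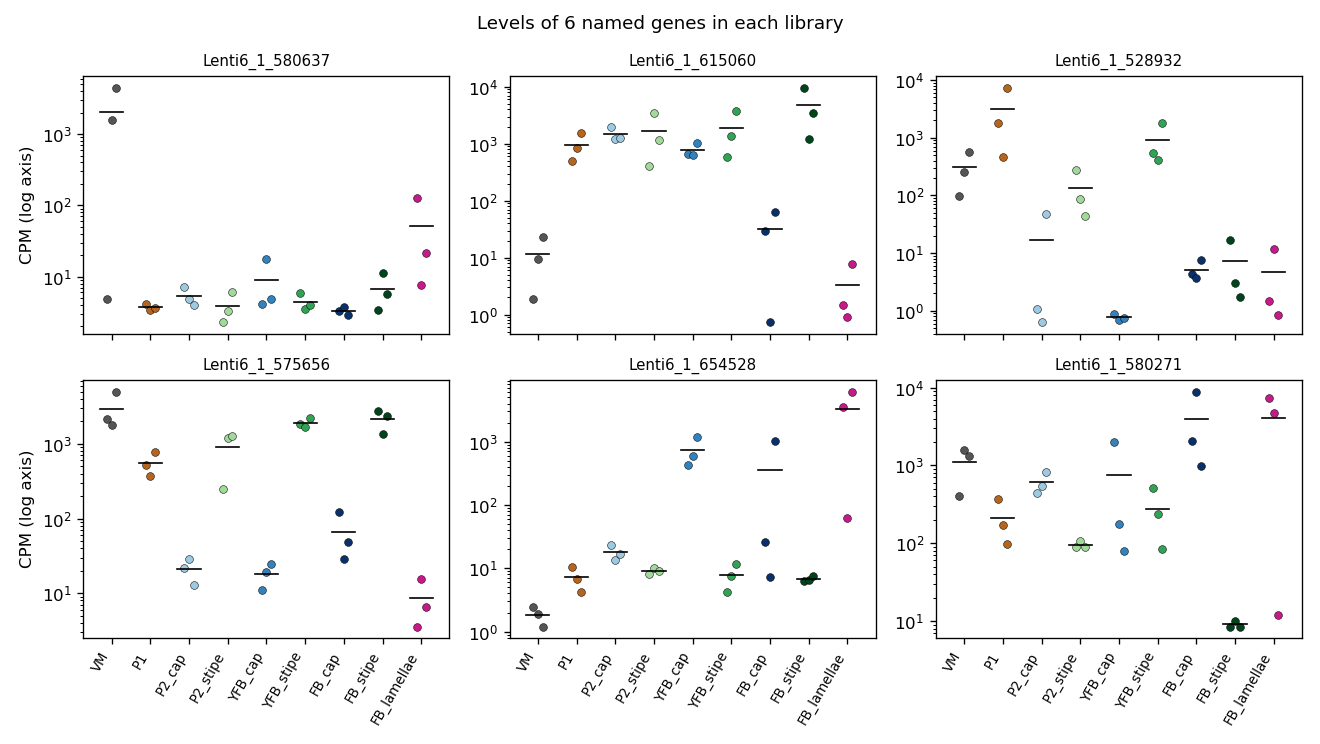
CPM (log axis) of 6 named genes in each library (points) by group, with a line at each group mean. Lenti6_1_575656 lies between 245 and 2789 CPM in the stipe libraries and between 3.57 and 122 CPM in the cap and lamellae libraries, and Lenti6_1_615060 is below 100 CPM in all VM, FB_cap and FB_lamellae libraries.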

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

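The test without the 100 genes with the most reads was set before its result was seen, and the tests without FB_cap replicate 2 and with flowcell as a covariate were read only after the result. The interactions for P2 to YFB and for YFB to FB were themselves added after seeing the data.

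The cap-to-stipe difference changed between stage 2 and the fruiting body for 1215 genes by a test of the difference itself. By the sign of the estimates alone, 619 of them were higher in the cap in the fruiting body and lower at stage 2, and 438 the reverse, but only 29 and 11 of all genes were called in these directions at both stages. The median absolute log2 difference was 1.90. With flowcell as a covariate the count was 126, and without 1 of P2_cap replicates 1 and 3, P2_stipe replicate 3, FB_cap replicate 2 and FB_stipe replicates 4 and 3 it was 581, 670, 661, 727, 620 and 606. None of 80 random regroupings of the 12 libraries gave as many (1 of 81 splits with the real one, highest other 511, median 0). Such regroupings also mix tissues and stages. They therefore do not test an interaction in the presence of tissue and stage differences, and no conclusion is drawn.

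The change from the young to the full fruiting body differed between cap and stipe for 3703 genes. By the sign of the estimates alone, 2046 of them rose in the cap and fell in the stipe, 1443 the reverse, and 214 had the same sign in both, but most did not pass in both tissues. Genes called in these directions in both tissues were 1.80 and 4.22 times those of independent lists (84.4 and 23.5 genes). No other split gave as many (1 of 81, highest other 3060, median 0), but these splits also mix tissues and stages and do not test the interaction alone. The high other value points to a strong structure among these 12 libraries. The change from stage 2 to the young fruiting body differed between the tissues for 1 gene, Lenti6_1_246303, and 5 of 81 splits gave as many (highest other 6), so chance is not excluded for that count. The gene, chosen after its values were seen, fell by 2.79 on the log2 scale in the cap and rose by 1.24 in the stipe (difference -4.03 ± 0.61 SE, edgeR adjusted p = 0.0173). Leaving out 1 library gave 0 to 19 genes, with 19 without YFB_cap replicate 1, 3 without P2_stipe replicate 1 or YFB_cap replicate 2, 2 without P2_cap replicate 1, and 0 without P2_cap replicate 2, P2_stipe replicate 2 or 3, YFB_cap replicate 3 or YFB_stipe replicate 1.

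For the YFB to FB pattern, FB_cap replicate 2 alone is argued against as the whole cause, since 2643 genes were called without it. Leaving out the 100 genes with the most reads (20.5% of reads) gave 3687 genes, but moved the scaling of no library by more than 0.05 (log2), so it decided nothing about abundant genes. Flowcell cannot be told apart from stage in part, since no flowcell held libraries of both YFB_cap and FB_cap. With flowcell as a covariate 1303 genes were past the threshold, 641 toward the cap and 662 toward the stipe, of which 1187 were among the 3703, and this fit links the stages through other groups only. A difference between the maturation of cap and stipe, which the design names, is therefore open beside a flowcell difference as a candidate explanation for part of the count.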

How the results depend on the processing

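The paired block, the runs without several libraries, 2 interactions and the counts for further pairs of groups were chosen after seeing the data. Among the settings run, 0 of 521 refits of the 36 named gene results turned a direction, 470 kept the call and 51 lost it. Of the 36, 16 were called in every setting. These genes were named for large folds and libraries without overlap between groups. Leaving out a library could thus hardly turn a direction, and the 0 is no measure of robustness. No called gene shared with another setting turned direction, except 2 genes of FB_cap against FB_stipe without FB_cap replicate 3. RLE size factors, no filter and unique reads kept every count within 1.5 times, except 9 genes with RLE for the P2 to YFB interaction. The counts over 9 groups (2833 to 3654 over the settings on all libraries), over 8 groups (1978 to 2510) and by RPKM (1841 to 2923) stayed within that range. With the replicate block the counts were 26 for YFB_cap against P2_cap, 708 for FB_stipe against YFB_stipe, 790 for FB_cap against FB_stipe, 216 for FB_lamellae against FB_cap, 469 for the FB against P2 interaction and 0 for P2 to YFB. The block, like the flowcell covariate, in effect drops FB_stipe replicate 4. Leaving out that library alone gave 880 for FB_stipe against YFB_stipe, 1023 for FB_cap against FB_stipe and 620 for FB against P2. Same-number libraries deviated together in all 3 pairs in 2 comparisons, and in some pairs elsewhere. In those 2 the paired block gave 0 and 2464 genes and changed no count by over 1.5 times. Every library correlated best with its own number in those 2 and in FB_stipe against YFB_stipe (2 pairs).

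With flowcell as a covariate the counts were 1167 (P1 against VM), 10 (YFB_cap against P2_cap), 347 (FB_cap against YFB_cap), 707 (FB_stipe against YFB_stipe), 134 (FB_cap against FB_stipe), 194 (FB_lamellae against FB_cap), 126 (FB against P2), 2 (P2 to YFB) and 1303 (YFB to FB). With limma-voom they were 68 (YFB_cap against P2_cap) and 5 (P2 to YFB), and with DESeq2 53 (P2_stipe against P1), 153, 657 (FB_lamellae against FB_cap) and 66. The 6 libraries alone gave 129 (YFB_cap against P2_cap), 552 (FB_cap against YFB_cap), 415 (FB_cap against FB_stipe) and 0 (FB_lamellae against FB_cap, 1028 at an unadjusted p under 0.05). Without FB_cap replicate 2 and FB_lamellae replicate 1 they were 1272 (FB_cap against YFB_cap) and 919 (FB_cap against FB_stipe), and without the 4 libraries of 1 flowcell 1078 (P1 against VM). The count without the 4 libraries of 1 flowcell rests on 1 VM library. The spread of VM is there assumed to be that of the other groups, so no conclusion is drawn from that count. The cause of these moves was not tested, apart from fewer samples in fits that drop libraries, in effect or outright.

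Leaving out 1 library at a time gave 1494 to 2684 genes for P1 against VM, 1167 to 1688 for P2_cap against P1, 0 to 2 for P2_stipe against P1, 5 to 57 for YFB_cap against P2_cap, 1138 to 2582 for FB_cap against YFB_cap, 505 to 1145 for FB_stipe against YFB_stipe, 593 to 1143 for P2_cap against P2_stipe, 1548 to 2656 for YFB_cap against YFB_stipe, 814 to 1934 for FB_cap against FB_stipe, 38 to 703 for FB_lamellae against FB_cap, 581 to 1521 for FB against P2, 0 to 19 for P2 to YFB and 2643 to 4087 for YFB to FB. Leaving out all libraries of 1 replicate number gave 2449 to 2768 for the RPKM rule. The planned tests of gene lists were not run, because no descriptions were paired with the identifiers. In the 11 comparisons, 14% to 24% of simulated 2-fold changes were recovered, so most changes of that size would be missed. Their median log2 estimates, 0.95 to 1.13, lay near the 2-fold cutoff of a call. The cutoff therefore limited recovery beside the 3 libraries per group.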

Other observations

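The test of mycelium mixed into a library, the counts for pairs of groups outside the 11 comparisons and the overlaps were chosen after seeing the data, while the predictions for a shared flowcell and for other splits were written before those results were seen.

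In the stage 1 primordium and the stipes a few genes took a larger share of the reads than in the other groups. The 5 genes with the most reads were taken in each library by itself. They took 10.6% ± 0.94 of the reads in P1, 12.7% ± 3.28 in P2_stipe, 14.7% ± 1.92 in YFB_stipe and 11.7% ± 1.12 in FB_stipe (SD, n = 3 each). They took 3.93% ± 0.22 in VM, 5.76% ± 0.85 in P2_cap, 4.50% ± 0.70 in YFB_cap, 7.61% ± 1.38 in FB_cap (up to 9.20% in 1 library, near the lowest P2_stipe library at 9.62%) and 2.78% ± 0.62 in FB_lamellae. Lenti6_1_580818, the gene with the most reads over all libraries, held 6.19% ± 0.574 of the reads in YFB_stipe and 0.319% ± 0.305 in FB_lamellae (SD, n = 3 each). Lenti6_1_604362 was likewise highest in YFB_stipe (2.89% ± 0.169) and lowest in FB_lamellae (0.135% ± 0.071). Lenti6_1_392744 had another order, highest in FB_stipe (2.76% ± 0.394) and lowest in VM (0.205% ± 0.02), with FB_cap (1.75% ± 0.737) above P1 (1.51% ± 0.22). Lenti6_1_580630 and Lenti6_1_580643 were also higher in FB_cap (1.34% ± 0.639 and 1.14% ± 0.597) than in P1 (0.763% ± 0.17 and 0.693% ± 0.118). The genes given by identifier were chosen by their reads over all libraries, and are not always the 5 with the most reads in a given library.

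The counts for further pairs of groups were mixed. Between YFB_stipe and P1 edgeR called 0 genes (520 at an unadjusted p under 0.05, and 0 also with RLE, with the replicate block and with flowcell as a covariate), and YFB_cap differed from P1 by 2564 genes (2544 with the replicate block and 2288 with flowcell as a covariate). FB_stipe differed from P2_stipe by 119 genes (7 with the replicate block and 8 with flowcell as a covariate) and from P1 by 2019 (1423 and 776). Both settings in effect drop FB_stipe replicate 4, so these falls cannot be read as replicate or flowcell effects alone. FB_cap differed from P1 by 1133 genes (1009 and 1071) and from YFB_stipe by 1131 (1021 and 351), against 2019 and 1212 for FB_stipe (1423 and 708 with the replicate block, 776 and 707 with flowcell as a covariate), so the order of the tissues depended on the setting. Genes that separated P2_cap from P1 also separated YFB_cap from YFB_stipe, in libraries the comparisons do not share. Of 1196 genes lower in P2_cap and 1569 lower in YFB_cap, 794 were shared, against 138.3 for independent lists, and of those higher 383 were shared, against 48.6. In opposite directions 2 and 0 genes were shared.

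Genes that fell from VM to P1 tended to be higher again in the mature cap. Of 1097 genes lower in P1 than VM and 1432 higher in FB_cap than YFB_cap, 368 were shared, against 115.8 for independent lists, while 28 genes rose at both steps, against 98.9, and 18 fell at both, against 62.5. Because FB_cap replicate 2 shares a flowcell with VM replicates 1 and 2, and FB_cap replicate 3 with VM replicate 3, the overlap was taken again in fits without a flowcell common to VM and FB_cap. It was 2.84 times that of independent lists with VM replicates 1 and 2 and FB_cap replicates 1 and 3, and 2.57 times with VM replicate 3 and FB_cap replicates 1 and 2. In the latter the lone VM library is assumed to vary like the other groups. A flowcell shared by VM and FB_cap is argued against as the whole cause. P1 replicate 3 and YFB_cap replicate 1 also shared a flowcell and stayed in both fits, so a shift common to them was not tested. No biological explanation was tested.

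FB_cap replicate 2 and FB_lamellae replicate 1 leaned toward VM on the first principal component, at -56.5 and -43.5. The other 4 libraries of their groups lay at -20.4 to 31.5. By correlation FB_lamellae replicate 3 stood apart, at 0.834 and 0.852 with replicates 1 and 2 (0.910 with each other). It correlated best with YFB_cap replicate 3 (0.912), and FB_cap replicate 2 with FB_lamellae replicate 2 (0.916, own group at most 0.879). FB_cap replicate 1 and FB_lamellae replicate 2, which shared a flowcell, correlated best with each other (0.916, own groups at most 0.907 and 0.910). Most FB_cap and FB_lamellae libraries thus correlated best outside their group. Libraries of P1 and P2_stipe also correlated best outside their group, and no cause was tested. A shift common to the flowcell of FB_cap replicate 2 and FB_lamellae replicate 1 was tested. The deviation of VM replicates 1 and 2 from VM replicate 3 correlated over 10258 genes with that of FB_cap replicate 2 from its group (0.392) and of FB_lamellae replicate 1 from its group (0.337), where genes are not independent replicates. These values are those a flowcell shift needs. With FB_cap replicates 1 and 3 in place of replicate 2 the values were -0.209 and -0.269. With FB_lamellae replicates 2 and 3 in place of replicate 1 they were -0.079 and -0.213. Deviations within a group offset each other, so these lower values are in part fixed by the positive ones. But libraries without a shared flowcell, picked from many pairs, reached 0.434 (FB_cap with FB_stipe) and 0.519 (P2_cap replicate 2 with P2_stipe replicate 2). The values therefore do not single out the flowcell. Mycelium mixed into these libraries was tested on 110 genes at least 8-fold higher in VM than in P1, P2, YFB and FB_stipe. The 10th percentile of their level was 2.43% of VM in FB_cap replicate 2 and 2.61% in FB_lamellae replicate 1. As predicted for a mixture, both lay above 1.46%, the highest library of those groups. They did not reach 2 times that value, the margin asked for a decision. The genes were chosen as low in those groups, with no such limit on FB_cap and FB_lamellae. A higher value in FB_cap or FB_lamellae is therefore no sign of a mixture by itself. FB_cap replicate 3 and FB_lamellae replicate 2 also lay above 1.46%, at 1.93% and 1.74%, so the test did not decide. It replaced an earlier test, the share of these genes far below the library's median level (under 0.25 of it), after that share was seen (13.6% and 18.2%). All 24 fruiting libraries met the earlier prediction of at most 18.2%, so it could not separate them. Both a mixture and a flowcell shift stay open, and no biological explanation was tested.

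For the 11 comparisons of 3 against 3 libraries, only 10 splits exist, too few for a share under 0.05. The real split gave the most genes in 8 of them (1 of 10 splits as large). The real and highest other counts were 2034 and 18 for P1 against VM, 1905 and 0 for P2_cap against P1, 44 and 2 for YFB_cap against P2_cap, 2205 and 0 for FB_cap against YFB_cap, 1212 and 0 for FB_stipe against YFB_stipe, 1056 and 0 for P2_cap against P2_stipe, 2499 and 0 for YFB_cap against YFB_stipe, and 1697 and 12 for FB_cap against FB_stipe. For P2_stipe against P1 and YFB_stipe against P2_stipe all 10 splits gave 0. For FB_lamellae against FB_cap, 2 of 10 splits gave as many as the real 327. The other, with 767 genes, set FB_cap replicate 2 with FB_lamellae replicates 1 and 2, and FB_lamellae replicate 3 with FB_cap replicates 1 and 3. It so kept together the libraries of the flowcell that also held VM replicates 1 and 2, and parted FB_lamellae replicate 3 from its group. This points to a structure of these samples. With flowcell as a covariate the real count was 194. No regrouping gave as many genes over the 9 groups (1 of 81 splits, real 3529, highest other 944). The same held over the 8 fruiting groups (1 of 81, real 2374, highest other 514). A share below 1 of 81 could not be reached with these splits. They mix tissues and stages, so they test only whether any groups differ, not which ones. They do not tell group and flowcell apart.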
